A study of Homo sapiens with 8 samples.

How the data were processed

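RNA of 2 human ovarian carcinoma cell lines was measured on Illumina beadchips of 47323 probes, with 2 arrays per line and treatment, 8 in all. Per the labels' protocols, the cells grew in RPMI medium with serum, were treated for 48 h with 10 µM lovastatin or with DMSO, total RNA was purified on columns with DNase treatment and checked on a Bioanalyser, and biotinylated cRNA was made with a MessageAmp kit. The labels do not say whether the 2 arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, plus the disagreement of the lines in the model of both lines. Having 2 arrays per group limits the precision. No scan, slide or date was given in the sources used here.

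The authors deposited a table of mean bead intensity per probe, neither background-subtracted nor normalized per the file headers and the values. The same deposited table gives a detection p-value for each probe and array, which sets its brightness against the array's negative controls. A second deposited table holds the authors' log2 values of the same arrays. Per the submitters' processing notes these were made with limma; its version and settings, and any image or summary software, are not given in the sources used here. Set against neqc normalization of each line's 4 arrays alone, 99.997% of the SKOV3 and 99.987% of the OVCAR5 values of the authors' deposited table lay within 0.01 log2, so the table was taken as log2, background-corrected and quantile-normalized within a line, uncentred. Its array medians were 4.81 in SKOV3 and 4.74 in OVCAR5, and 1 value was missing.

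The main values were computed from the intensities of all 8 arrays together with neqc of limma 3.58.1 in R 4.3.3: normal-exponential background correction with the background inferred from the detection p-values, quantile normalization and log2 with an offset of 16. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes took their genes from the platform annotation: 30113 had 1 gene symbol, 8 several and 17202 were unnamed here. Of the probes with 1 symbol, 30074 matched a current gene record. Probes with 1 symbol and a detection p under 0.01 on at least 2 arrays were kept (14851 probes), and each gene was represented by its brightest kept probe, which left 11218 of 20046 genes. Of 2950 genes with several kept probes, 1587 were called in SKOV3 and 678 in OVCAR5, and 159 and 71 of these had probes of opposite sign. Of the named genes with several kept probes, 46 were called in SKOV3 and 27 in OVCAR5, and 23 and 11 of these had a probe more than 1.5-fold from the one used. The text gives the other probe for only some of them.

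Limma's moderated test was fitted to 4 group means over the 8 arrays, so that the groups shared one estimate of the spread, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were lovastatin against DMSO in each line, the difference of these changes, and the lines in DMSO; a model with line and treatment as additive terms gave the change over both lines. Lists of genes (39, of pathways, complexes and cell types) and the tests of these contrasts were fixed before the data were examined. Camera with a preset correlation of 0.01 tested each list with at least 5 tested genes against the other genes, adjusted over the lists of a contrast, and was repeated with an estimated correlation. Fry, which tests whether the members of a list move on balance one way and not against other genes, was below an adjusted p of 0.05 for 35 of 37 lists in SKOV3, 30 in OVCAR5 and 25 for the difference; over both lines it was so for 33, and between the lines in DMSO for 36.

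The genes named in the text follow a rule. For each lovastatin comparison these were the 8 with the highest and the 8 with the lowest log2 fold change among called genes that were detected on both arrays of at least 1 group and had both lovastatin arrays on the same side of both DMSO arrays. For the difference between lines and for the lines in DMSO these were the 5 highest and 5 lowest. From each list up to 4 members with the largest absolute change were eligible. HMGCS1, INSIG1, SQLE, ABCA1, KLF2, KLF6, CCN1, CCN2, CDKN1A, MKI67 and MAP1LC3B were always eligible; 2 further genes of that kind had no probe with a gene name here and were not analysed here. A further list, which stays in the counts of lists, and its genes are not reported here. Genes named outside the rule are said to have been singled out after their values were seen.

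The steps were tested on simulated values of the 11218 genes with known changes in a small set of them. In each simulation 67 genes were changed by 0.5 log2, 67 by 1 and 66 by 2, far fewer than were called in the data. With so few, the Benjamini-Hochberg adjustment is stricter than in the data. For the model of both lines the change was equal in both. The rates below are therefore not the sensitivity reached in the data. Of 67 genes changed by 1 log2, 92.5% were called for SKOV3, 95.5% for OVCAR5, 31.3% for the difference between lines, 100% over both lines and 91.0% for the lines in DMSO, and 0 were called with the wrong sign; of 67 changed by 0.5 log2, 19.4%, 13.4%, 5.97%, 61.2% and 13.4% were called. In the same order, 11, 9, 5, 15 and 7 unchanged genes were called, which made 7.24%, 6.12%, 5.26%, 7.94% and 4.90% of the calls, against the 5% aimed at. In the SKOV3 simulation 1 of 1 shifted list and 0 of 36 others were called by camera. The simulated genes varied independently of each other, so this cannot show how often camera calls lists whose genes are correlated. Alternatives were the authors' log2 values, quantile normalization without background correction (offset 1), median scaling, cyclic loess, no detection filter, a detection p under 0.05, the mean of a gene's probes, an intensity trend with robust variance, a threshold of 2-fold, each array left out, the replicate number as a block, each line's arrays alone, and the mean of the lines' contrasts. Control probes were not used here. Coordinates are not given, since no genome build is named in the sources used here.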

Results

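Gene expression was measured on beadchip arrays in SKOV3 and OVCAR5, human ovarian carcinoma cell lines, after 48 h with 10 µM lovastatin, a statin that blocks the mevalonate pathway, or with its solvent DMSO. Each of the 4 groups held 2 arrays. Between 15370 and 17231 of the 47323 probes of an array were detected at p under 0.01, and the 95th percentile of signal lay at 13.7 to 17.3 times the median of the undetected probes. The arrays of a group correlated at r = 0.988 (SKOV3 lovastatin) to 0.994 (SKOV3 DMSO) across the 11218 tested genes, which are not independent replicates. Over the same genes, the log2 difference between the arrays of a group had an SD of 0.342 in SKOV3 lovastatin and of 0.239 to 0.262 in the other groups. The number of arrays limits the precision of every value. Changes are given as log2 fold change ± standard error with n = 2 arrays per group, lovastatin minus DMSO, and p-values are limma's, adjusted by Benjamini-Hochberg over 11218 tested genes. For each gene named as risen or fallen, both lovastatin arrays lay beyond both DMSO arrays. Counts of list members are out of those tested and use the adjustment over all genes, and the count adjusted over the list alone is given where it differs. Where every array of a group left a gene undetected, a bound is given as at least a fold: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own.

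The first comparison asked how blocking the mevalonate pathway changed expression in SKOV3 cells. MMP10, a secreted protease of the extracellular matrix, rose by 6.57 ± 0.13 (adjusted p = 1.1e-07), and the interleukin gene IL1A rose by 5.0 ± 0.28, detected on 1 of 2 SKOV3 DMSO arrays (adjusted p = 4.6e-06). The stress genes GDF15, a secreted member of the TGF-beta family, and INHBE, an inhibin subunit, were at least 49.8-fold higher (adjusted p = 9.1e-08) and at least 25.1-fold higher (adjusted p = 4.1e-07). THBS1, the matrix glycoprotein thrombospondin, changed by -5.19 ± 0.19 (adjusted p = 9.8e-07) and EDN1, which encodes the vasoconstrictor endothelin, by -5.09 ± 0.20 (adjusted p = 1.2e-06). CCN1 and CCN2, matricellular targets of the co-activator YAP, fell too, at -4.32 ± 0.17 and -4.27 ± 0.11 (adjusted p = 1.2e-06 and 3.6e-07). Of the 11218 genes, 5665 changed, 2986 upward and 2679 downward, and 2047 of them by at least 2-fold (1094 higher, 953 lower).

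Among the other genes with the largest changes in SKOV3, RN7SK, a small nuclear RNA that restrains transcription elongation, rose by 5.82 ± 0.17 and RNA5S9, a ribosomal RNA gene with many near-identical copies which the probe cannot be assumed to separate, by 5.20 ± 0.16. NUPR1, a stress-inducible chromatin protein, rose by 4.75 ± 0.26, and IFI27, an interferon-stimulated gene, was at least 21.1-fold higher (adjusted p = 1.2e-06). IGFBP3, which binds insulin-like growth factors, changed by -4.0 ± 0.18. Genes lost from detection were ANKRD1, another YAP target (at least 18.6-fold lower, adjusted p = 4.1e-07), E2F2, a transcription factor of S-phase entry (at least 12.3-fold lower, adjusted p = 2.0e-06), and ZBED2 (at least 12.7-fold lower, adjusted p = 3.6e-07).

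**Figure D1:**
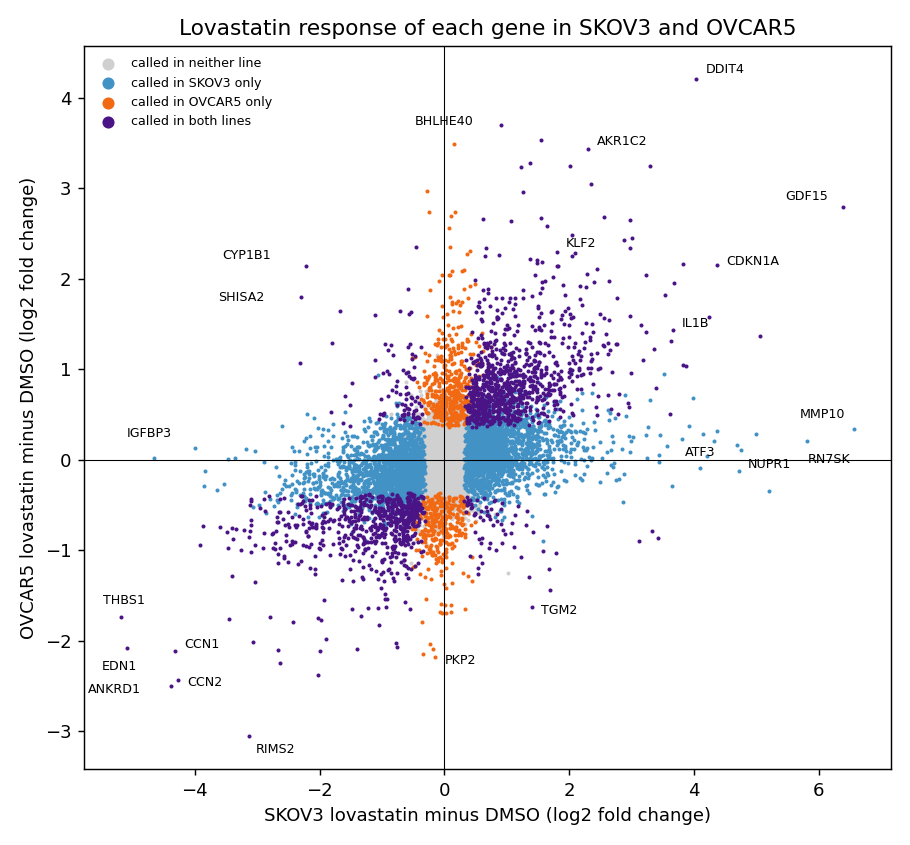
Each point is 1 of 11218 genes, placed by its log2 fold change with lovastatin in SKOV3 (horizontal axis) and in OVCAR5 (vertical axis), and coloured by the line or lines in which it was called at an adjusted p under 0.05. DDIT4 lies far out on both axes (4.04 and 4.21), while MMP10, undetected in OVCAR5, rose by 6.57 in SKOV3; some plotted values belong to groups at background, for which the text gives bounds.

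Sterol lists were called upward in SKOV3 with the preset correlation and not with an estimated one. Among the enzymes of cholesterol synthesis, 11 of 17 rose and 1 fell (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00200, 0.116 with an estimated correlation). MSMO1, a sterol demethylating oxidase, rose by 1.85 ± 0.13, MVD and HMGCS1, enzymes of the mevalonate pathway, by 1.48 ± 0.18 and 1.48 ± 0.12, and SQLE, squalene epoxidase, by 1.18 ± 0.19 (adjusted p = 1.0e-03). Of the genes of sterol uptake and SREBP2 control, 6 of 8 rose and 1 fell (camera adjusted p = 0.0274, 0.148 with an estimated correlation). NPC1, the lysosomal cholesterol transporter, rose by 2.0 ± 0.17, and INSIG2 and INSIG1, sterol sensors of the endoplasmic reticulum, by 1.82 ± 0.16 and 1.79 ± 0.12; TMEM97, which binds NPC1, changed by -1.06 ± 0.13 on its brightest probe and by 0.66 on the other. ABCA1, which exports cholesterol and is induced by oxysterols through LXR, changed by -2.15 ± 0.15, detected on 1 of 2 SKOV3 lovastatin arrays (adjusted p = 1.1e-05).

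Most tested Krueppel-like factor genes rose in SKOV3. Of the Krueppel-like factors, 7 of 9 rose and 0 fell (camera adjusted p = 0.0120, 0.122 with an estimated correlation). KLF9 rose by 2.04 ± 0.26, KLF2, a factor known to respond to statins in endothelium, by 1.80 ± 0.16, KLF6 by 1.12 ± 0.12, and KLF4 by 2.40 ± 0.33, detected on 1 of 2 SKOV3 DMSO arrays. Of the conserved targets of YAP and TAZ, 10 of 22 fell and 4 rose (camera adjusted p = 0.0274, 0.145 with an estimated correlation). The members that rose included TGM2, transglutaminase, singled out after its value was seen, at 1.40 ± 0.18 on the brightest of its probes and as low as -0.98 on another. TAGLN, an actin-binding protein on the list of SRF targets, changed by -3.10 ± 0.20 (adjusted p = 7.8e-06).

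**Figure D2:**
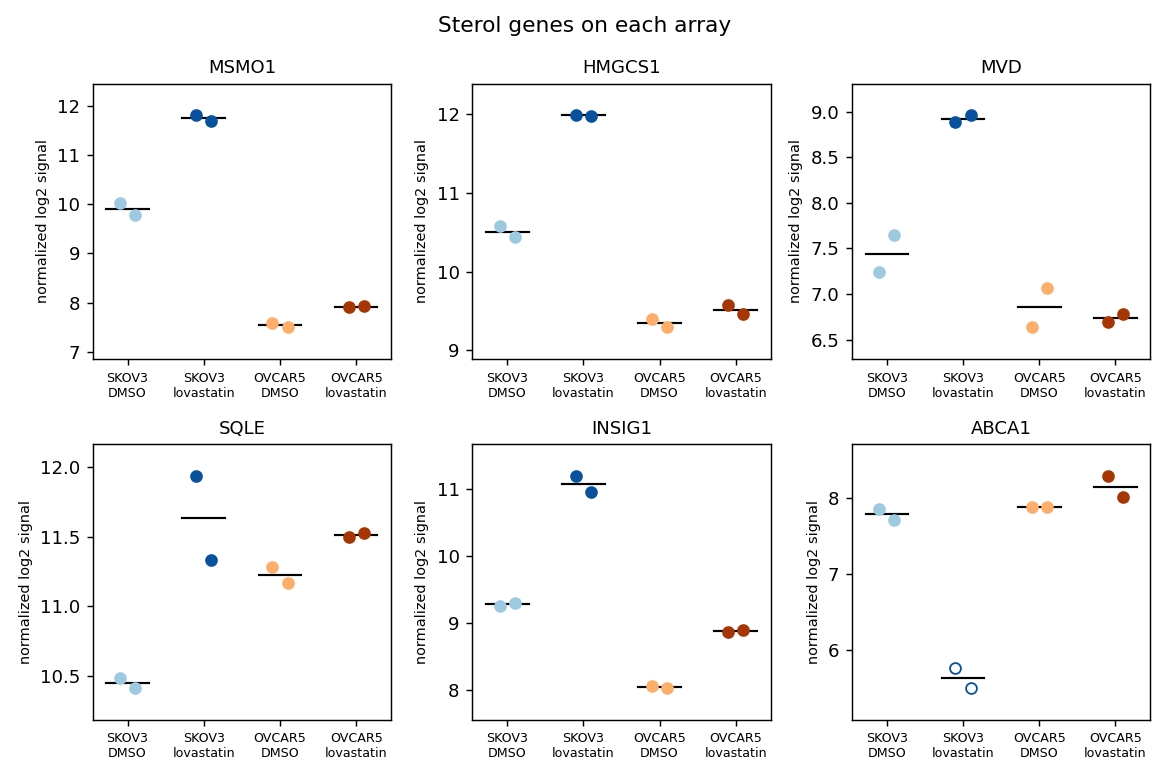
Log2 normalized intensity (vertical axes) of MSMO1, HMGCS1, MVD, SQLE, INSIG1 and ABCA1 in each group (horizontal axes); each point is 1 array, each bar the mean of 2 arrays, and open points mark groups not detected on both arrays. In SKOV3 MSMO1 changed by 1.85 and HMGCS1 by 1.48, and in OVCAR5 their values were 0.37 and 0.17 (adjusted p = 0.0694 and 0.354).

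Cell cycle genes fell in SKOV3. In the list of mitotic genes, 36 of 36 fell and 0 rose (camera adjusted p = 5.0e-22, 0.0115 with an estimated correlation). The mitotic kinesin KIF20A changed by -3.54 ± 0.11, CDCA3 by -3.09 ± 0.13, the survivin gene BIRC5 by -2.95 ± 0.14 and cyclin A2, encoded by CCNA2, by -2.88 ± 0.12. The proliferation marker MKI67 was at least 2.03-fold lower (adjusted p = 9.1e-05). In the list of S-phase and replication genes, 30 of 33 fell and 0 rose (camera adjusted p = 2.4e-17, 0.0370 with an estimated correlation). MCM10, a replication initiation factor, and UHRF1, which maintains DNA methylation, changed by -3.41 ± 0.13 and -3.40 ± 0.13, and RRM2, a subunit of ribonucleotide reductase, by -3.88 ± 0.13, detected on 1 of 2 SKOV3 lovastatin arrays. CDKN1A, which encodes the CDK inhibitor p21, rose by 4.38 ± 0.14 (adjusted p = 6.6e-07), and CDKN1C was at least 3.08-fold higher (adjusted p = 1.5e-05). In the list of ribosome biogenesis genes and MYC targets, 22 of 26 fell and 1 rose (camera adjusted p = 8.2e-08, 0.0370 with an estimated correlation). MYC itself changed by -2.89 ± 0.14, the nucleolar factors RRS1 and BOP1 by -2.22 ± 0.12 and -1.75 ± 0.14, and RRP9, another nucleolar factor, by 1.68 ± 0.15.

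Genes of the integrated stress response, which ATF4 drives when translation is restrained, mostly rose in SKOV3. In that list, 20 of 23 rose and 0 fell (camera adjusted p = 2.3e-10, 0.0553 with an estimated correlation). Besides NUPR1, the transcription factors DDIT3 and ATF3 rose by 4.24 ± 0.15 and 4.15 ± 0.30, and DDIT4, an inhibitor of mTORC1, by 4.04 ± 0.12 (adjusted p = 4.8e-07). Among autophagy genes, 15 of 26 rose and 1 fell (camera adjusted p = 2.4e-04, 0.0718 with an estimated correlation). WIPI1 rose by 3.15 ± 0.11, GABARAPL1 by 2.59 ± 0.15, the kinase gene ULK1 by 2.23 ± 0.14 and MAP1LC3B, which encodes a core protein of the autophagosome membrane, by 1.87 ± 0.13. Among lysosomal genes, 11 of 22 rose and 1 fell (camera adjusted p = 0.0190, 0.122 with an estimated correlation). The protease gene CTSD rose by 1.88 ± 0.14, the sialidase gene NEU1 by 1.67 ± 0.15 and PSAP, the saposin precursor, by 1.64 ± 0.12.

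**Figure D3:**
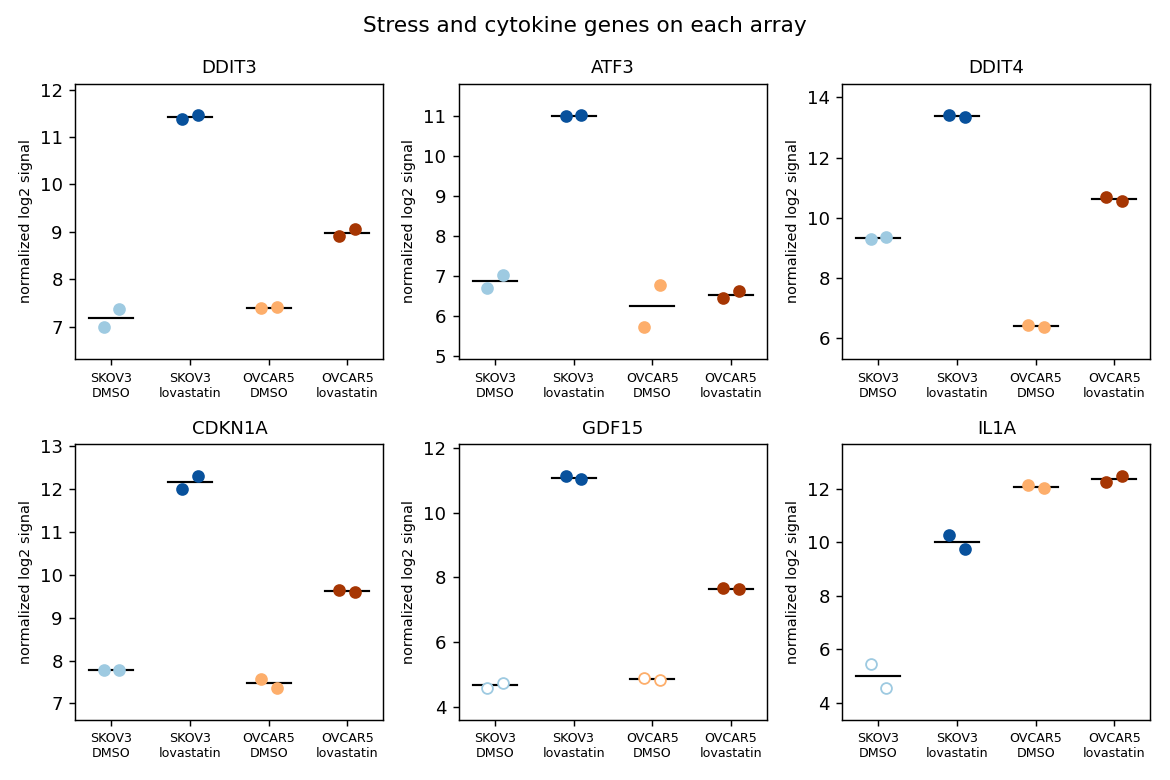
Log2 normalized intensity (vertical axes) of DDIT3, ATF3, DDIT4, CDKN1A, GDF15 and IL1A in each group (horizontal axes), with arrays as points, the mean of 2 arrays as bars and open points for groups not detected on both arrays. CDKN1A rose by 4.38 in SKOV3 and 2.15 in OVCAR5, and ATF3 by 4.15 in SKOV3 against a value of 0.28 in OVCAR5 (adjusted p = 0.553).

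Inflammatory and immediate early genes moved both ways in SKOV3. In the NF-kB and cytokine list, 14 of 19 rose and 3 fell (camera adjusted p = 0.00127, 0.0957 with an estimated correlation). IL1B was at least 7.51-fold higher (adjusted p = 6.6e-07) and the NF-kB subunit gene RELB at least 4.97-fold higher (adjusted p = 4.3e-06), and the cytokine gene IL32 rose by 2.97 ± 0.13. IL6, the interleukin 6 gene, singled out after its value was seen, went the other way at -2.20 ± 0.21, detected on 1 of 2 SKOV3 lovastatin arrays (adjusted p = 6.9e-05). Among AP-1 and immediate early genes, 14 of 23 rose and 2 fell (camera adjusted p = 4.4e-04, 0.122 with an estimated correlation). The ETS factor gene ETV5 and the phosphatase gene DUSP5, both targets of MAP kinase signalling, rose by 3.62 ± 0.14 and 2.45 ± 0.15. In the list of genes beside ERBB2, which SKOV3 cells are known to carry in extra copies, 7 of 10 rose and 1 fell (camera adjusted p = 0.00936, 0.122 with an estimated correlation). The adaptor gene GRB7 rose by 2.71 ± 0.26, PPP1R1B by 2.23 ± 0.19 and STARD3, a cholesterol-binding protein of endosomes, by 1.63 ± 0.16.

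Adhesion and secretory lists were called upward in SKOV3, and respiratory chain and ribosomal protein lists downward. Among integrins and focal adhesion genes, 13 of 19 rose and 1 fell (camera adjusted p = 0.00175, 0.0957 with an estimated correlation); ITGA3 rose by 1.89 ± 0.14 and ITGA6 by 1.76 ± 0.16, and CAV1, the caveola coat gene, changed by -1.42 ± 0.17. Among epithelial adhesion genes, 6 of 15 rose and 1 fell (camera adjusted p = 0.0283, 0.148 with an estimated correlation); the plakoglobin gene JUP rose by 2.10 ± 0.15 and the keratin gene KRT19 by 1.89 ± 0.12. Among genes of vesicle coats and ER to Golgi traffic, 9 of 22 rose and 0 fell (8 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0191, 0.226 with an estimated correlation); SEC24D, a coat subunit, rose by 1.54 ± 0.20. Of the respiratory chain genes, 7 of 27 fell and 0 rose (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0274, 0.255 with an estimated correlation), UQCRB by -0.96 ± 0.14. Of the ribosomal protein genes, 12 of 30 fell and 1 rose (0 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0274, 0.291 with an estimated correlation), RPS7 by -1.84 ± 0.19.

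The other lists were not called as groups in SKOV3 by camera, although single members passed. Fatty acid synthesis had 4 higher and 1 lower of 14 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.384). LXR targets, the genes oxysterols switch on, had 1 higher and 4 lower of 8 (camera adjusted p = 0.149). Prenyl chain enzymes, which make and attach the lipids that anchor proteins in membranes, had 3 higher and 4 lower of 14 (camera adjusted p = 0.210). Ras and Rab GTPases had 9 higher and 2 lower of 18 (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.210). SRF targets had 4 higher and 6 lower of 19 (camera adjusted p = 0.192). CDK inhibitors had 4 higher and 1 lower of 5 (camera adjusted p = 0.109). p53 targets had 7 higher and 5 lower of 19 (camera adjusted p = 0.325). Interferon-stimulated genes had 7 higher and 4 lower of 22 (camera adjusted p = 0.366). Camera's adjusted p was 0.143 for apoptosis regulators, 0.305 for the unfolded protein response, 0.143 for heat shock genes, 0.195 for NRF2 targets and 0.666 for mesenchymal and matrix genes. It was 0.109 for hypoxia and glycolysis genes, 0.861 for histone genes, 0.653 for Muellerian and ovarian carcinoma markers, 0.659 for leukocyte markers and 0.702 for fibroblast markers. Histone genes and fibroblast markers had medians of 0.12 and 0.07, means of -0.10 and -0.20 while camera placed both downward. Among members that passed, HMOX1, heme oxygenase, rose by 2.27 ± 0.12, VEGFA, a growth factor of vessels, by 2.27 ± 0.37, the fatty acid desaturase gene SCD by 1.52 ± 0.12, and CD68, a marker of macrophages and of lysosomes, by 2.04 ± 0.15. The BH3-only genes HRK and PMAIP1 were at least 6.40-fold higher (adjusted p = 2.5e-05) and changed by 1.96 ± 0.16.

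Structural RNAs were looked at after RN7SK and RNA5S9 had been seen among the largest changes. Over all 120 structural RNAs tested, 38 rose and 36 fell, with a median of -0.07 and a camera p of 0.895. The 25 of them other than small nucleolar RNAs, a narrower class chosen after that, had 20 that rose and 0 that fell, a median of 1.57 and an unadjusted camera p of 4.6e-09 (0.0604 with an estimated correlation).

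Camera with a preset correlation of 0.01 called 19 of the 37 lists with at least 5 tested genes in SKOV3, 13 upward and 6 downward. With an estimated correlation 3 of them kept an adjusted p under 0.05: S phase, mitosis and ribosome biogenesis.

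The second comparison put the same question to OVCAR5 cells. DDIT4 rose by 4.21 ± 0.12 (adjusted p = 2.4e-06) and BHLHE40, a circadian and hypoxia-responsive repressor, by 3.70 ± 0.19 (adjusted p = 2.2e-05). The steroid-metabolising aldo-keto reductases AKR1C2 and AKR1C4, whose near-identical sequences leave the gene uncertain, rose by 3.44 ± 0.13 and 3.25 ± 0.19, and THBD, the thrombin receptor thrombomodulin, by 3.24 ± 0.11. The YAP targets ANKRD1 and CCN2 fell, at -2.5 ± 0.12 and -2.44 ± 0.11 (adjusted p = 1.5e-05 and 1.4e-05). Of the 11218 genes, 2558 changed, 1516 upward and 1042 downward, 608 of them by at least 2-fold (436 higher, 172 lower).

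Among the other largest changes in OVCAR5, the ion channel gene CALHM3 was at least 5.62-fold higher (adjusted p = 3.7e-06) and APCDD1L rose by 3.28 ± 0.23, detected on 1 of 2 OVCAR5 DMSO arrays. RIMS2, a gene of vesicle release, was at least 5.69-fold lower (adjusted p = 1.1e-05) and SERTAD4 at least 2.5-fold lower (adjusted p = 1.2e-04). The long noncoding RNA SFTA1P changed by -2.37 ± 0.18, VSTM1, an immunoglobulin-type receptor gene, by -2.25 ± 0.13, PPME1, a methylesterase gene, by -2.15 ± 0.14, and PKP2, a desmosome protein, by -2.18 ± 0.15, detected on 1 of 2 OVCAR5 lovastatin arrays.

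The sterol genes were not called as a group in OVCAR5. Of the cholesterol synthesis genes, 1 of 17 rose and 0 fell (camera adjusted p = 0.763, 0.786 with an estimated correlation). LSS, lanosterol synthase, was the gene that rose, at 0.83 ± 0.14 on the brightest of its probes and as low as 0.06 on another. HMGCS1 and SQLE had values of 0.17 ± 0.12 (adjusted p = 0.354) and 0.29 ± 0.19 (adjusted p = 0.316). Of the genes of sterol uptake and SREBP2 control, 3 of 8 rose and 1 fell (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.149, 0.248 with an estimated correlation). NPC1 and INSIG1 rose by 1.07 ± 0.17 and 0.84 ± 0.12, and TMEM97 changed by -1.32 ± 0.13 on its brightest probe and by 0.01 on the other. ABCA1 had a value of 0.26 ± 0.15 (adjusted p = 0.239).

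Ras and Rab genes and Krueppel-like factors were called upward as lists in OVCAR5 with the preset correlation and not with an estimated one. In the Ras and Rab list, 7 of 18 rose and 1 fell (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00331, 0.101 with an estimated correlation); the secretory Rab gene RAB27B was at least 2.55-fold higher (adjusted p = 3.3e-05) and RRAS rose by 0.95 ± 0.17. Of the Krueppel-like factors, 5 of 9 rose and 0 fell (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00391, 0.110 with an estimated correlation): KLF2 rose by 2.30 ± 0.16, KLF13 by 1.63 ± 0.19 and KLF6 by 1.37 ± 0.12. Of the YAP and TAZ targets, 11 of 22 fell and 0 rose (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 3.3e-06, 0.0461 with an estimated correlation). CCN1 changed by -2.12 ± 0.17 and TGM2 by -1.62 ± 0.18.

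**Figure D4:**
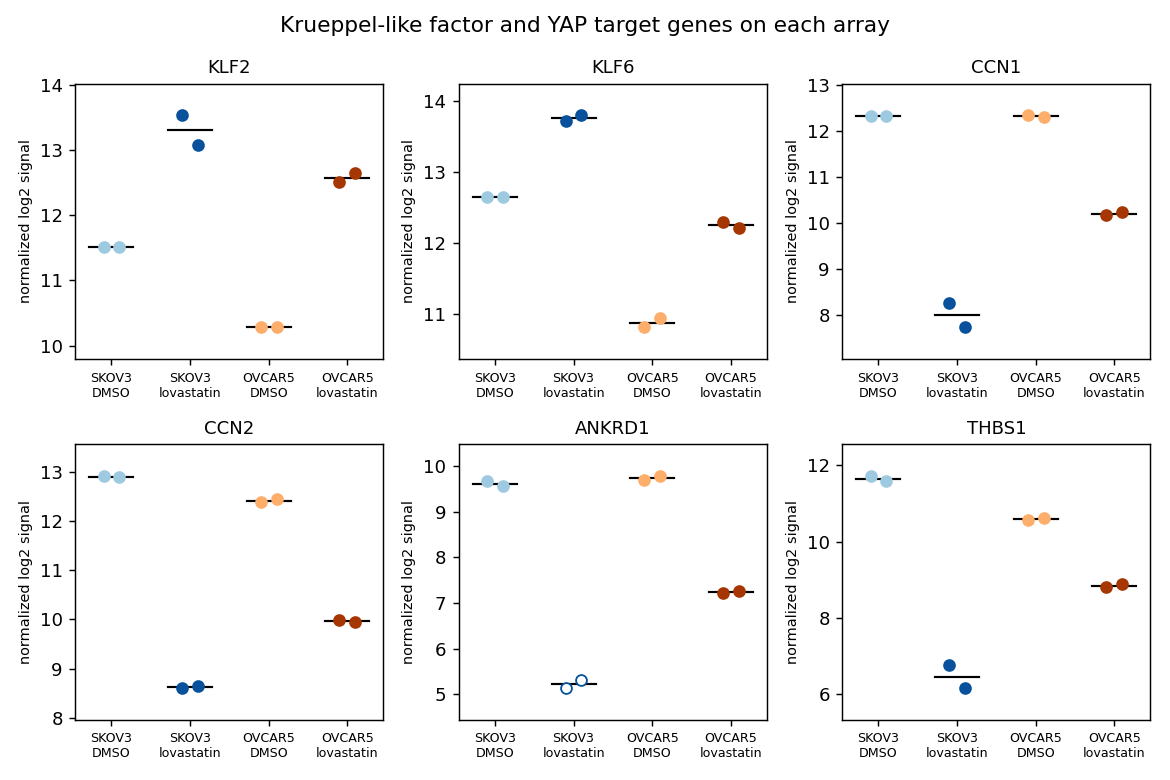
Log2 normalized intensity (vertical axes) of KLF2, KLF6, CCN1, CCN2, ANKRD1 and THBS1 in each group (horizontal axes); points are arrays, bars are means of 2 arrays, and open points mark groups not detected on both arrays. KLF2 and KLF6 rose in both lines, by 1.80 and 1.12 in SKOV3 and 2.30 and 1.37 in OVCAR5, while THBS1 changed by -5.19 in SKOV3 and -1.74 in OVCAR5.

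Cell cycle genes fell in OVCAR5 too. In the S-phase list, 28 of 33 fell and 0 rose (0 higher and 30 lower adjusted over the list alone, camera adjusted p = 2.2e-15, 0.0412 with an estimated correlation). The replication licensing gene CDT1 changed by -1.35 ± 0.24, MCM10 by -1.28 ± 0.13 and CDC6 by -1.48 ± 0.18, detected on 1 of 2 OVCAR5 lovastatin arrays. In the mitotic list, 11 of 36 fell and 0 rose (0 higher and 13 lower adjusted over the list alone, camera adjusted p = 9.2e-07, 0.0412 with an estimated correlation), with MKI67 at -1.33 ± 0.17 and CDCA8 at -0.94 ± 0.16. Of the CDK inhibitors, 3 of 5 rose and 1 fell (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0150, 0.130 with an estimated correlation); CDKN1A rose by 2.15 ± 0.14 and CDKN1C was at least 4.67-fold higher (adjusted p = 3.3e-05). Of the ribosome biogenesis genes, 15 of 26 fell and 0 rose (0 higher and 19 lower adjusted over the list alone, camera adjusted p = 2.2e-09, 0.0412 with an estimated correlation), with RRP9 at -1.21 ± 0.15 and MYBBP1A, a nucleolar protein gene, at -1.06 ± 0.19. Of the histone genes, 7 of 12 rose and 0 fell (camera adjusted p = 0.00636, 0.116 with an estimated correlation); H2BC5 rose by 1.15 ± 0.13.

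Stress and metabolic lists were called upward in OVCAR5. Of the NRF2 antioxidant genes, 9 of 15 rose and 0 fell (camera adjusted p = 1.0e-05, 0.130 with an estimated correlation). HMOX1 rose by 1.91 ± 0.12, GCLC, an enzyme of glutathione synthesis, by 1.67 ± 0.15, and the aldo-keto reductase AKR1B10 was at least 3.68-fold higher (adjusted p = 1.4e-05). Of the hypoxia and glycolysis genes, 8 of 25 rose and 1 fell (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.1e-04, 0.130 with an estimated correlation), with NDRG1 at 2.45 ± 0.14 and the glucose transporter gene SLC2A3 at 1.97 ± 0.12. Autophagy genes included 10 of 26 that rose and 0 that fell (11 higher and 0 lower adjusted over the list alone, camera adjusted p = 6.0e-04, 0.0699 with an estimated correlation); OPTN, an autophagy receptor, rose by 1.77 ± 0.19 and MAP1LC3B by 0.98 ± 0.13. Of the lysosomal genes, 8 of 22 rose and 0 fell (camera adjusted p = 1.7e-04, 0.0633 with an estimated correlation), CTSD by 1.60 ± 0.14. Of the integrated stress response genes, 6 of 23 rose and 2 fell (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0597, 0.248 with an estimated correlation), a list not called here; DDIT3 rose by 1.58 ± 0.15.

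Some inflammatory, integrin and secretory genes rose in OVCAR5, and their lists were called with the preset correlation and not with an estimated one. In the NF-kB and cytokine list, 7 of 19 rose and 0 fell (9 higher and 0 lower adjusted over the list alone, camera adjusted p = 5.7e-05, 0.0631 with an estimated correlation). The chemokine gene CXCL8 rose by 2.58 ± 0.13 and PTGS2, which encodes an inducible cyclooxygenase, by 2.25 ± 0.13. Of the interferon-stimulated genes, 11 of 22 rose and 1 fell (11 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00507, 0.203 with an estimated correlation), ISG20 by 2.43 ± 0.16 and OASL by 1.71 ± 0.12. Of the AP-1 and immediate early genes, 10 of 23 rose and 1 fell (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.4e-04, 0.130 with an estimated correlation), JUND by 2.21 ± 0.12. Of the integrins and focal adhesion genes, 9 of 19 rose and 0 fell (11 higher and 0 lower adjusted over the list alone, camera adjusted p = 8.6e-04, 0.0763 with an estimated correlation); ITGB4, a hemidesmosome integrin, was at least 2.95-fold higher (adjusted p = 1.4e-05) and ITGA2 rose by 1.29 ± 0.14. Of the genes of vesicle coats and ER to Golgi traffic, 5 of 22 rose and 0 fell (camera adjusted p = 0.0244, 0.199 with an estimated correlation), SEC24D by 0.84 ± 0.20.

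Other lists were not called as groups in OVCAR5. Of fatty acid synthesis genes there were 2 higher and 0 lower of 14 (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.988). LXR targets included 1 higher and 2 lower of 8 (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.584). Prenyl chain enzymes included 1 higher and 1 lower of 14 (camera adjusted p = 0.405). SRF targets included 2 higher and 5 lower of 19 (camera adjusted p = 0.0968). p53 targets included 5 higher and 1 lower of 19 (camera adjusted p = 0.0558). Epithelial adhesion genes included 6 higher and 2 lower of 15 (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0528). Camera's adjusted p was 0.611 for apoptosis regulators, 0.250 for the unfolded protein response, 0.188 for heat shock genes, 0.0968 for mesenchymal and matrix genes and 0.986 for respiratory chain genes. It was 0.407 for ribosomal protein genes, 0.905 for Muellerian and ovarian carcinoma markers, 0.739 for ERBB2 amplicon genes, 0.0850 for leukocyte markers and 0.875 for fibroblast markers. The median, mean and camera direction, which differed in sign, were -0.03, 0.03 and up for fatty acid synthesis, 0.02, -0.19 and down for LXR targets, and 0.02, 0.02 and down for respiratory chain genes. Limma called 0 respiratory chain, ribosomal protein and fibroblast marker genes, and 1, 2 and 0 had an unadjusted p under 0.05. Members that passed included JUP at 2.28 ± 0.15, CD68 at 0.95 ± 0.15 and CSF1R, a macrophage growth factor receptor, at least 2.53-fold higher (adjusted p = 2.4e-04). Other probes of JUP and CD68 were as low as 0.31 and 0.33. In all, 18 of 37 lists were called in OVCAR5, 14 upward and 4 downward, and 4 of them kept an adjusted p under 0.05 with an estimated correlation: YAP and TAZ targets, S phase, mitosis and ribosome biogenesis.

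Without OVCAR5 DMSO replicate 1 or 2 the count of changed genes in OVCAR5 was 1400 or 1360, and without OVCAR5 lovastatin replicate 1 or 2 it was 1274 or 1369. Without SKOV3 lovastatin replicate 1 or 2 it was 3319 or 3233. With median scaling in place of quantile normalization the median of all genes moved to 0.10 log2, and 1583 genes were higher and 530 lower. With the OVCAR5 arrays alone 3410 of 9825 genes were called, against 4980 of 10393 with the SKOV3 arrays alone. The counts of the 2 lines thus lie closer when the lines do not share a spread.

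A further comparison asked which changes the lines shared. In the model of both lines with 8 arrays, CDKN1A rose by 3.27 ± 0.40 (adjusted p = 0.00124), DDIT4 by 4.13 ± 0.10 (adjusted p = 6.8e-07), and TSC22D3, a glucocorticoid-induced leucine zipper gene, by 3.0 ± 0.31 (adjusted p = 6.6e-04). The probes of TSC22D3 ran from 3.17 to 4.29 in SKOV3 and from 0.20 to 2.28 in OVCAR5. CCN1, CCN2 and THBS1 fell, at -3.22 ± 0.40, -3.35 ± 0.33 and -3.46 ± 0.61 (adjusted p = 0.00135, 5.3e-04 and 0.00504). CDC25A, a phosphatase that activates cyclin-dependent kinases, had a value of -2.60 ± 0.32 (adjusted p = 0.00119), from at least 7.81-fold lower in SKOV3 and -1.76 ± 0.15 in OVCAR5. Another of its probes changed by -0.98 in SKOV3. This model called 3557 genes, 1940 higher and 1617 lower, 948 of them by at least 2-fold (535 higher, 413 lower). It has no term for a different response of the lines, so its standard errors and p-values also hold the disagreement between them.

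The other genes with the largest changes over both lines were GDF15, INHBE, THBD, MMP10 and RN7SK upward and EDN1, ANKRD1, RIMS2 and PLAC8 downward. GDF15 and INHBE were at least 4.33-fold higher (adjusted p = 1.1e-05) and at least 1.43-fold higher (adjusted p = 4.0e-04) in OVCAR5, and THBD was at least 5.38-fold higher in SKOV3 (adjusted p = 6.6e-07). MMP10 was not detected on any OVCAR5 array, and RN7SK had a value of 0.20 there (adjusted p = 0.443). EDN1 was at least 2.16-fold lower in OVCAR5 (adjusted p = 3.3e-04), and PLAC8, a placenta-enriched gene, at least 4.78-fold lower in SKOV3 (adjusted p = 1.2e-06).

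Genes called in each line moved the same way more often than independent lists of those sizes would: 940 rose in both against 403.5 and 651 fell in both against 248.8. Opposite calls numbered 69 (higher in SKOV3, lower in OVCAR5) against 277 and 89 the other way against 362. Without OVCAR5 DMSO replicate 1 or 2 the genes called in both lines the same way numbered 906 or 886, and without OVCAR5 lovastatin replicate 1 or 2 846 or 894. The lines had separate controls. Across genes, which are not independent replicates, the fold changes correlated at Pearson r = 0.481 and a Spearman coefficient of 0.488, with a slope of 0.284 for OVCAR5 on SKOV3. KLF2, KLF6, CDKN1A, DDIT4, NDRG1, ISG20, CTSD and MAP1LC3B were among the genes called upward in both lines, and CCN1, CCN2, ANKRD1, THBS1, MCM10, CDCA3 and MKI67 among those called downward.

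Over both lines camera called 22 lists, 17 upward and 5 downward, and with an estimated correlation 0, with 10 at an unadjusted p under 0.05. The Krueppel-like factors (6 higher and 0 lower of 9, camera adjusted p = 0.00151, 0.110 with an estimated correlation) and autophagy genes (12 higher and 0 lower of 26, 13 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.4e-04, 0.149 with an estimated correlation) were called upward. The YAP and TAZ targets (1 higher and 9 lower of 22, 3 higher and 11 lower adjusted over the list alone, camera adjusted p = 7.3e-04, 0.0964 with an estimated correlation) and S-phase genes (0 higher and 29 lower of 33, 0 higher and 30 lower adjusted over the list alone, camera adjusted p = 7.2e-13, 0.233 with an estimated correlation) were called downward. The mean of the 2 lines' separate contrasts called 5787 genes; without SKOV3 DMSO replicate 1 or 2 the pooled count was 2179 or 2108.

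**Figure D5:**
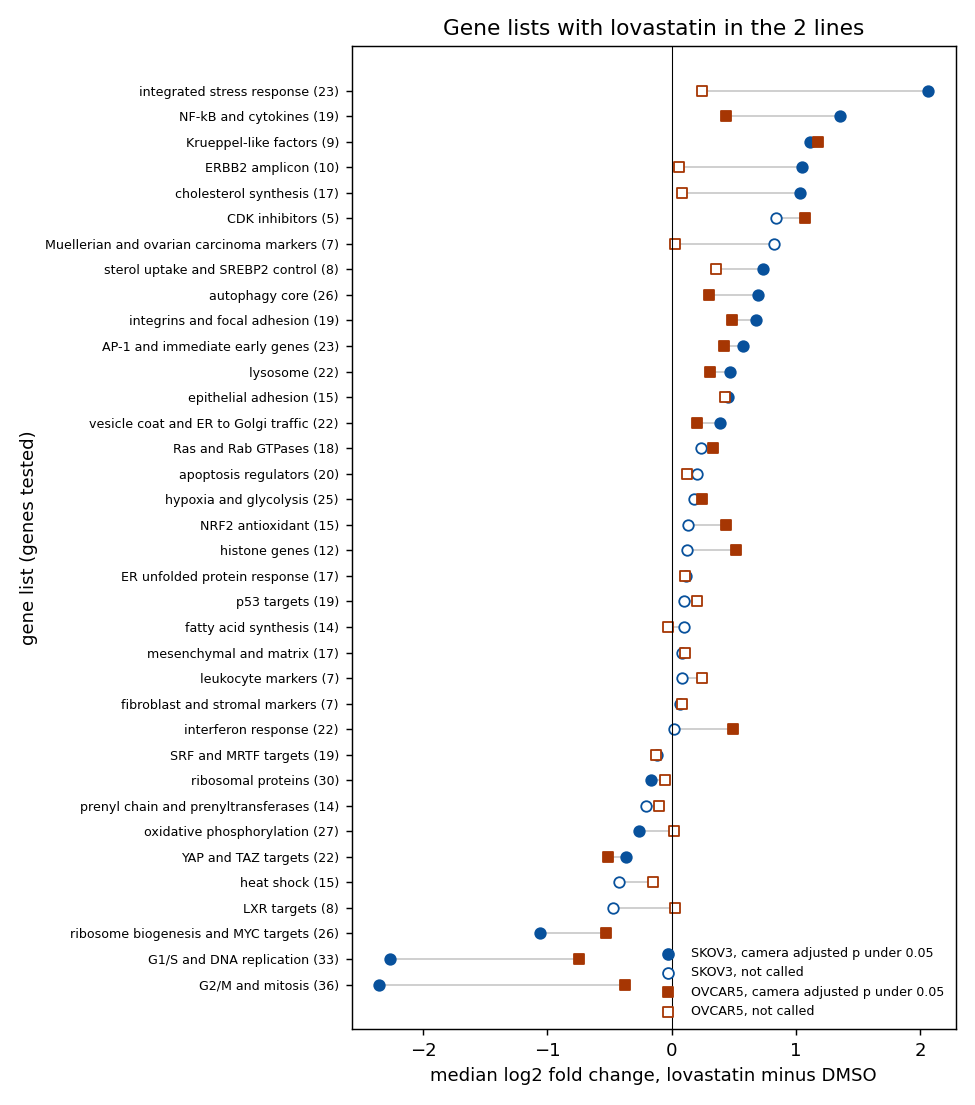
Median log2 fold change with lovastatin (horizontal axis) of the tested genes of each list reported here (vertical axis, number tested in brackets), as circles for SKOV3 and squares for OVCAR5, filled where camera's adjusted p was under 0.05. The mitotic list lies at -2.35 in SKOV3 and -0.38 in OVCAR5, and the integrated stress response list at 2.06 and 0.24; values at background enter these medians as measured.

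Next came a test of whether the response differed between the lines, as the change in SKOV3 minus the change in OVCAR5. The change of MMP10 was higher in SKOV3 by 6.22 ± 0.19 (adjusted p = 5.7e-06) and that of RN7SK by 5.61 ± 0.24 (adjusted p = 2.0e-05), with RNA5S9, IFI27 and IL1A next at 5.54 ± 0.23, 4.85 ± 0.26 and 4.72 ± 0.40. CYP1B1, a cytochrome P450 that oxidises estrogens, changed by -2.22 ± 0.20 in SKOV3 and 2.14 ± 0.20 in OVCAR5, a difference of -4.36 ± 0.28 (adjusted p = 6.7e-05). IGFBP3, at -4.12 ± 0.26 (adjusted p = 6.3e-05), fell in SKOV3 and was not detected in OVCAR5. Of the 11218 genes, 3062 differed, 1439 with the higher change in SKOV3 and 1623 with the lower, 1622 of them by at least 2-fold (734 and 888).

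The other genes at the low end were ZBED2 (-4.68 ± 0.17), SHISA2, a regulator of receptor maturation (-4.09 ± 0.16), and KIT, a receptor tyrosine kinase (-3.71 ± 0.27). SHISA2 was at least 3.58-fold lower in SKOV3 (adjusted p = 2.6e-06) and rose by 1.80 ± 0.11 in OVCAR5. Fitted differences of genes at background in a group, such as ZBED2, SHISA2 and IFI27, were not bounds.

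In the mitotic list, 34 of 36 had a lower change in SKOV3 and 0 had a higher one (0 higher and 35 lower adjusted over the list alone, camera adjusted p = 1.8e-23, 0.0101 with an estimated correlation). KIF20A differed by -3.27 ± 0.15, CENPF, a kinetochore protein gene, by -2.62 ± 0.16 and CCNA2 by -2.45 ± 0.17. In the S-phase list, 26 of 33 had a lower change in SKOV3 and 1 had a higher one (1 higher and 27 lower adjusted over the list alone, camera adjusted p = 2.8e-13, 0.0698 with an estimated correlation); RRM2 differed by -3.14 ± 0.18 and TYMS, thymidylate synthase, by -2.67 ± 0.17. Of the integrated stress response genes, 17 of 23 had a higher change in SKOV3 and 1 had a lower one (camera adjusted p = 1.1e-10, 0.0698 with an estimated correlation); NUPR1 differed by 4.65 ± 0.37, ATF3 by 3.87 ± 0.42 and TRIB3, a pseudokinase gene, by 2.84 ± 0.22. Of the cholesterol synthesis genes, 8 of 17 had a higher change in SKOV3 and 0 had a lower one (camera adjusted p = 0.00220, 0.183 with an estimated correlation); MVD differed by 1.60 ± 0.26, MSMO1 by 1.48 ± 0.18 and CYP51A1, a sterol demethylase, by 1.46 ± 0.29. Of the genes of sterol uptake and SREBP2 control, 4 of 8 had a higher change in SKOV3 and 0 had a lower one (camera adjusted p = 0.0275, 0.199 with an estimated correlation), INSIG2 by 1.37 ± 0.22 and INSIG1 by 0.95 ± 0.18.

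Of the ERBB2 amplicon genes, 5 of 10 had a higher change in SKOV3 and 1 had a lower one (camera adjusted p = 0.0222, 0.187 with an estimated correlation), with GRB7 at 2.52 ± 0.37. Of the autophagy genes, 11 of 26 had a higher change in SKOV3 and 1 had a lower one (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0147, 0.183 with an estimated correlation), with WIPI1 at 1.66 ± 0.16 and SQSTM1, the receptor p62, at 1.23 ± 0.17. Of the ribosome biogenesis genes, 9 of 26 had a lower change in SKOV3 and 2 had a higher one (camera adjusted p = 0.0275, 0.187 with an estimated correlation); MYC differed by -2.86 ± 0.19 and RRP9 by 2.89 ± 0.21. Of the histone genes, 3 of 12 had a lower change in SKOV3 and 0 had a higher one (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0124, 0.183 with an estimated correlation), with H2AX, a variant that marks DNA breaks, at -1.37 ± 0.42. Of the respiratory chain genes, 3 of 27 had a lower change in SKOV3 and 0 had a higher one (camera adjusted p = 0.0498, 0.410 with an estimated correlation), with UQCRB at -1.08 ± 0.19. Outside the called lists, TGM2 differed by 3.03 ± 0.26 on the brightest of its probes. The changes of its probes ran from -0.98 to 1.40 in SKOV3 and from -1.62 to -0.57 in OVCAR5. In all 10 of 37 lists were called, 5 each way, and with an estimated correlation the call of 1 held, that of the mitotic genes.

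Of 1591 genes called in both lines the same way, 1072 changed more in SKOV3; the difference itself was called for 479, 418 of them larger in SKOV3. The count of shared genes was 846 to 906 when any 1 OVCAR5 array was left out. Of 3916 genes called in SKOV3 and not in OVCAR5, 1968 had a called difference, and of 809 called in OVCAR5 and not in SKOV3, 383 did. Without SKOV3 DMSO replicate 1 the test called 2037 genes, and 2037 without replicate 2. Median scaling moved the median of all genes to -0.16 log2 and gave 758 higher and 1597 lower calls.

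A last comparison described how the lines differed in DMSO, as SKOV3 minus OVCAR5. SPANXC, SPANXD and SPANXA1, cancer-testis genes whose near-identical copies the probes cannot be assumed to separate, were at least 368-fold higher, at least 296-fold higher and at least 311-fold higher in SKOV3 (adjusted p = 6.2e-09, 3.4e-09 and 3.4e-09), and SPANXA2 was higher by 8.98 ± 0.30, detected on 1 of 2 OVCAR5 DMSO arrays. DHRS2, a short-chain dehydrogenase gene, was at least 297-fold higher in SKOV3 (adjusted p = 1.1e-08). CLDN11, a tight junction claudin, and IGFBP4, which binds insulin-like growth factors, were at least 344-fold lower and at least 116-fold lower (adjusted p = 3.4e-09 and 1.3e-08). The paralogous respiratory chain genes UQCRH and UQCRHL, which the probes cannot be assumed to separate, were at least 309.6-fold lower (adjusted p = 3.0e-09) and at -7.76 ± 0.17. The bound of UQCRH rests on the brightest of its probes. Of the 11218 genes, 6940 differed, 3619 higher and 3321 lower in SKOV3, 3404 of them by at least 2-fold (1889 higher, 1515 lower).

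The list of Muellerian and ovarian carcinoma markers was not called between the lines: 5 of 7 were higher in SKOV3 and 1 was lower (camera adjusted p = 0.0952, 0.324 with an estimated correlation). PAX8, a transcription factor of the tubal epithelium, was higher in SKOV3 by 3.79 ± 0.17, and FOLR1, a folate receptor, and SOX17 were at least 16.5-fold higher (adjusted p = 4.7e-08) and at least 8.58-fold higher (adjusted p = 2.7e-08). Of the ERBB2 amplicon genes, 7 of 10 were higher in SKOV3 and 2 were lower (camera adjusted p = 0.0952, 0.324 with an estimated correlation); the receptor gene ERBB2 was higher by 4.61 ± 0.12 (adjusted p = 2.3e-08) and PPP1R1B at least 50.4-fold higher (adjusted p = 4.0e-08). Of the ribosome biogenesis genes, 20 of 26 were lower and 0 were higher in SKOV3 (0 higher and 21 lower adjusted over the list alone, camera adjusted p = 1.7e-05, 0.179 with an estimated correlation), the 1 list of 37 that camera called. Markers of other cells were not called as groups either. Of the leukocyte markers, 5 of 7 were lower and 0 were higher in SKOV3 (camera adjusted p = 0.0952, 0.324 with an estimated correlation). Of the fibroblast markers, 6 of 7 were higher in SKOV3 and 0 were lower (camera adjusted p = 0.0952, 0.324 with an estimated correlation). LAPTM5, a lysosomal protein of blood cells, was at least 9.0-fold lower and MFAP5, a microfibril protein, at least 17-fold higher in SKOV3 (adjusted p = 9.2e-08 and 5.3e-07). Of the 4 endothelial markers tested, too few for a list test, 3 were lower in SKOV3, and 1 rose with lovastatin in SKOV3 and 1 in OVCAR5. Of the 19 gut epithelium markers with a probe, 18 were detected on no array; ANXA10, an annexin of gastric epithelium, was detected on both OVCAR5 lovastatin arrays and on no other. Median scaling moved the median of all genes to 0.21 log2 and gave 4145 higher and 2292 lower calls.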

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

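The tests on structural RNAs, and those of an inactive drug and of a ceiling for sterol genes, were chosen only after the result was seen. The count over other splits of the arrays and the comparison with matched random lists were set before. No group held 4 arrays, so single arrays could not be tested as outliers.

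Over both lines lovastatin against DMSO gave 3557 called genes. Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted with line as a term, 1, the real one, gave as many. The highest other split gave 7. The other splits left the lovastatin effect in the spread, which holds their counts down: 1 of them had 1603 genes at an unadjusted p under 0.05 and 0 called. The lowest share possible was 1 of 34, so the count cannot exclude chance. Such splits say nothing about differences between cultures, which the labels do not describe.

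Structural RNAs other than small nucleolar RNAs were higher with lovastatin in SKOV3: 20 of 25 rose, with a median of 1.57 log2, while in OVCAR5 0 rose and 5 fell, and the difference was called higher for 21. This class was set after the wider class of 120 structural RNAs had been tested and had not risen as a class (38 higher, 36 lower). The tables argue against the normalization as the whole source, since the lowest median over 4 other ways of preparing the values was 0.954, and against 1 array alone, since the smaller rise of the 2 lovastatin arrays was 1.55. Whether the labelled RNA held a lower share of messenger RNA cannot be decided. Small nucleolar RNAs, which also lack a poly(A) tail, had a median of -0.224 in SKOV3, with 18 higher and 36 lower. They fell with lovastatin in OVCAR5 too, at a median of -0.59, so they are no neutral measure. Their change was higher in SKOV3 for 31 and lower for 8, with a median difference of 0.29. Unequal RNA integrity, for which no value was used here, and an effect of lovastatin in this line stay open, so the rise may be technical or biological.

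Sterol synthesis genes were called higher as a list in SKOV3 (camera adjusted p = 0.00200, 0.116 with an estimated correlation) and not in OVCAR5. The difference itself was called (camera adjusted p = 0.00220, adjusted p = 0.183 with an estimated correlation), so both calls depend on the correlation used. An inactive drug in the OVCAR5 samples is argued against by the fall of the YAP and TAZ targets there (camera adjusted p = 3.3e-06, 0.0461 with an estimated correlation). A ceiling would have these genes already at the induced level in OVCAR5. OVCAR5 DMSO minus SKOV3 lovastatin had a median of -1.33 log2 over the 17 genes, with 14 lower and 3 higher. This was within the SD over genes of 1.74, the limit set for this test. The mean was -1.11 with a standard error over genes of 0.42. Most of the genes thus lay below the level of SKOV3 with lovastatin, but their spread leaves a ceiling open for some. A smaller response of OVCAR5 in all genes stays a candidate explanation: of 10000 random lists matched on the SKOV3 change, a share of 0.129 had an OVCAR5 median as low as the list's 0.09, against a median of 0.23 with the central 95% of lists at -0.01 to 0.50. A difference between the lines in sterol regulation stays open too.

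The response differed between the lines in 3062 genes by the test of the difference, which is what picked out the values in this and the next paragraph. The lists that camera called for the difference, of which only that of mitosis kept the call with an estimated correlation, had positive median differences, SKOV3 minus OVCAR5, of 0.90 for cholesterol synthesis, 0.54 for sterol uptake and SREBP2 control, 1.70 for integrated stress response, 0.40 for autophagy core and 0.80 for ERBB2 amplicon. The negative ones were -1.55 for G1/S and DNA replication, -1.87 for G2/M and mitosis, -0.26 for oxidative phosphorylation, -0.45 for ribosome biogenesis and MYC targets and -0.53 for histone genes.

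Among the genes named in the text, the difference in log2 fold change, SKOV3 minus OVCAR5, passed the test for those that follow. Values of genes at background in a group are fitted values and not bounds. MMP10 (6.22), RN7SK (5.61), RNA5S9 (5.54), IFI27 (4.85), IL1A (4.72), NUPR1 (4.65), ATF3 (3.87), INHBE (3.69) and GDF15 (3.61) had the highest differences. HRK (3.47), ETV5 (3.11), TGM2 (3.03), RRP9 (2.89), TRIB3 (2.84), DDIT3 (2.66), GRB7 (2.52), PPP1R1B (2.39) and IL32 (2.38) came next among the positive differences. IL1B (2.23), CDKN1A (2.23), RELB (2.21), PKP2 (2.03), KLF4 (1.98), DUSP5 (1.95), MMP7 (1.92), SPRY2 (1.82) and PPME1 (1.81) had smaller positive differences. MMP1 (1.74), WIPI1 (1.66), TSC22D3 (1.65), PMAIP1 (1.65), MVD (1.60), KRT19 (1.57), MSMO1 (1.48), CYP51A1 (1.46) and STARD3 (1.40) were also higher in SKOV3 by this measure. DUSP6 (1.40), INSIG2 (1.37), HMGCS1 (1.31), SQSTM1 (1.23), ITGA3 (1.2), GABARAPL1 (1.2), SCD (1.10), CD68 (1.09) and PSAP (1.01) followed these. ULK1 (1.0), INSIG1 (0.95), ATF4 (0.94), NEU1 (0.93), NPC1 (0.92), ITGA6 (0.92), SQLE (0.90) and MAP1LC3B (0.89) had the smallest positive differences. ZBED2 (-4.68), CYP1B1 (-4.36), IGFBP3 (-4.12), SHISA2 (-4.09), KIT (-3.71), THBS1 (-3.45), CALHM3 (-3.34), KIF20A (-3.27), RRM2 (-3.14) and EDN1 (-3.01) had the lowest differences. MFAP5 (-2.98), E2F2 (-2.97), MYC (-2.86), BHLHE40 (-2.79), IL6 (-2.71), TYMS (-2.67), UHRF1 (-2.64), CENPF (-2.62), AKR1B10 (-2.57) and CCNA2 (-2.45) came next among the negative differences. CDCA3 (-2.43), BIRC5 (-2.42), ABCA1 (-2.42), CCN1 (-2.21), MCM10 (-2.13), TAGLN (-2.08), SLC2A3 (-2.05), ITGB4 (-2.03), MMP3 (-1.95) and APCDD1L (-1.91) had smaller negative differences. ANKRD1 (-1.89), MT1G (-1.85), CCN2 (-1.83), CSF1R (-1.71), FOLR1 (-1.71), AKR1C3 (-1.71), CDC25A (-1.69), CDT1 (-1.69), RAB27B (-1.67) and PTGS2 (-1.60) were also lower in SKOV3 by this measure. CDCA8 (-1.54), BOP1 (-1.47), OASL (-1.46), RPS7 (-1.38), H2AX (-1.37), RRS1 (-1.26), AKR1C4 (-1.24), CAV1 (-1.24), AKR1C2 (-1.13) and UQCRB (-1.08) followed on the negative side. MT2A (-1.07), PLAC8 (-1.06), CXCL8 (-0.93), JUND (-0.73), ANXA10 (-0.68) and H2BC5 (-0.61) had the negative differences nearest to 0. The difference of PLAC8 was 0.52 with quantile normalization without background correction (offset 1). That of TGM2 rests on the brightest of its probes, and another changed by -0.98 in SKOV3.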

How the results depend on the processing

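No test here was chosen after the result was seen. Every total count of called genes was within 1.5 times of the reported one under other normalizations, filters, probe summaries and variance models, though median scaling took the lower calls in OVCAR5 from 1042 to 530 and the higher ones for the difference from 1439 to 758. The authors' deposited log2 values gave 5690 called genes in SKOV3 and 2643 in OVCAR5. Each line's arrays alone gave 4980 of 10393 genes in SKOV3 and 3410 of 9825 in OVCAR5. A 2-fold threshold, stricter by construction, left 2047 genes in SKOV3, 608 in OVCAR5, 1622 for the difference, 948 over both lines, 3404 between the lines in DMSO and 264 shared. The labels do not tie the replicate number to a culture or day. Each array's deviation from its group mean was compared between the DMSO and lovastatin arrays of the same number. Across genes these deviations correlated at 0.227 in SKOV3 and -0.0265 in OVCAR5. As a block, the replicate number gave 1855 genes over both lines, 5819 in SKOV3, 2567 in OVCAR5, 3151 for the difference and 6375 in DMSO. The mean of the lines' contrasts gave 5787 over both lines, with all 3557 of the additive model among them. Its fit of 4 group means takes the disagreement of the lines out of the spread, where the additive model leaves it. The cause of the other shifts was not tested. With an estimated correlation the called lists numbered 3 in SKOV3, 4 in OVCAR5, 1 for the difference, 0 over both lines and 0 in DMSO by camera, with 10 and 1 at an unadjusted p under 0.05 in the last pair. Median scaling raised the share of higher calls from 59.3% to 74.9% in OVCAR5 and from 52.1% to 64.4% in DMSO and lowered it from 47.0% to 32.2% for the difference. It moved the median of all genes to 0.10 log2 in OVCAR5, -0.16 for the difference and 0.21 in DMSO, against 0.00 in SKOV3. Leaving out single arrays, the lone array being assumed to vary like the other groups, gave 4244 to 5436 genes in SKOV3, 1274 to 3319 in OVCAR5, 2037 to 3357 for the difference, 2108 to 3226 over both lines, 5828 to 7349 in DMSO and 846 to 1910 shared. It gave 17 to 19, 18 to 20, 8 to 10, 18 to 21 and 1 called lists in the order used above. Shared calls without OVCAR5 DMSO replicate 1 or 2 numbered 906 or 886, and without OVCAR5 lovastatin replicate 1 or 2 846 or 894. OVCAR5 had 1400, 1360, 1274 and 1369 genes without these arrays in turn. Without SKOV3 DMSO replicate 1 or 2 the difference had 2037 in either case and the fit of both lines 2179 or 2108. Without SKOV3 lovastatin replicate 1 or 2 OVCAR5 had 3319 or 3233. A group left with 1 array adds nothing to the spread that the groups share. Between the arrays of SKOV3 lovastatin the log2 difference had the largest SD, 0.342, and the OVCAR5 arrays stay in place without one of them. How much of these changes the shared spread accounts for was not tested. Some named genes changed sign. With quantile normalization without background correction, for the difference DDIT4 went from -0.17 to 0.66, JUP from -0.18 to 0.59, KLF9 from -0.21 to 0.58, PLAC8 from -1.06 to 0.52, THBD from 0.06 to -0.90 and VSTM1 from -0.38 to 0.70. With the mean of a gene's probes, in SKOV3 UQCRH went to 0.50. With that line's arrays alone, in SKOV3 UQCRH went to 1.11. The cause was not tested. Over the named genes and all alternatives other than left-out arrays, 7456 values kept sign and side of the threshold, 236 lost a call and 125 gained one; with an array left out 5627 kept, 279 lost and 74 gained. For single lists these counts were 1819, 75 and 27, and 1440, 32 and 8. Slide as a block was not run, since no slide is given in the sources used here, and the lines in DMSO were not compared in the authors' values, which were normalized per line. Signal near background limits the folds of dim genes.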

Other observations

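The groups in this part were chosen after their values were seen, and their camera p-values, adjusted over 18 such tests, are no independent evidence. These include tests of a group of 4 genes, below the least size of 5 used for lists, which is not given here. With an estimated correlation camera called 0 of these tests (lowest adjusted p = 0.0900), with 9 at an unadjusted p under 0.05. Genes that ERK signalling induces as its own feedback went up with lovastatin in SKOV3: of 14 tested, 10 rose and 1 fell (camera adjusted p = 4.6e-04). SPRY2, an inhibitor of receptor tyrosine kinase signalling, rose by 2.23 ± 0.16, DUSP6, an ERK phosphatase, by 1.37 ± 0.20 on its brightest probe and 0.13 on the other, and EPHA2, an ephrin receptor, changed by -0.58 ± 0.18. In OVCAR5 7 rose and 1 fell (camera adjusted p = 0.0141), with EPHA2 at -1.30 ± 0.18. The change was higher in SKOV3 for 9 and lower for 1 (camera adjusted p = 9.4e-04).

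Of 9 matrix metalloproteinases, enzymes that cut collagen and other matrix proteins, 5 rose in SKOV3 (camera adjusted p = 0.00566) and 2 in OVCAR5 (camera adjusted p = 0.0971). The collagenase gene MMP1 rose by 3.69 ± 0.27 in SKOV3 and was at least 3.02-fold higher in OVCAR5 (adjusted p = 0.00177). MMP7, the matrilysin gene, rose by 2.03 ± 0.13 in SKOV3 and was not detected in OVCAR5, and MMP3, a stromelysin gene, rose by 2.04 ± 0.16 in OVCAR5 and was not detected in SKOV3. Aldo-keto reductases, which reduce steroids and lipid aldehydes, rose in both lines, 4 of 5 in SKOV3 and 4 in OVCAR5 (camera adjusted p = 0.00855 and 3.9e-05). AKR1C3 rose by 1.25 ± 0.11 in SKOV3 and 2.96 ± 0.11 in OVCAR5, and the change was lower in SKOV3 for 4 of the 5 (camera adjusted p = 0.00647). The AKR1C sequences are close and the probes cannot be assumed to separate them. The smallest called rise in SKOV3 was 0.44 ± 0.16 (limma adjusted p = 0.0488), and AKR1B10 was not detected in that line.

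Metallothioneins, small proteins that bind zinc and copper, fell in SKOV3, 5 of 6 tested (camera adjusted p = 0.00580). MT2A changed by -1.12 ± 0.12 and MT1G by -1.91 ± 0.16, though these sequences are close and the probes cannot be assumed to separate them. In OVCAR5 limma called 0 of them (1 at an unadjusted p under 0.05, camera adjusted p = 0.935), MT2A being at -0.05 ± 0.12 (adjusted p = 0.827), and the change was lower in SKOV3 for 5 (camera adjusted p = 0.00240).

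Small nucleolar RNAs, which guide chemical marks on ribosomal RNA, went down in OVCAR5: of 95 tested, 50 fell and 0 rose, with a median of -0.59 (unadjusted camera p = 4.3e-17, 0.00685 with an estimated correlation). In SKOV3 36 fell and 18 rose. These RNAs lack a poly(A) tail and no RNA integrity value was used here, so their changes may be technical or biological. The 4011 detected probes without a gene name here were fitted on their own. In SKOV3 1339 were called, 539 of them higher, and in OVCAR5 328, 169 of them higher; the difference between lines was called for 509.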
